A study of Mus musculus with 2 samples.

How the data were processed

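DNase-seq had been run on 2 libraries of embryonic mouse liver at 13.5 days, 1 per biological replicate, per the labels. Both carry the same strain, tissue, age and donor label, so they form 1 group of 2 replicates, and sex is labelled as not collected. What the A85 YAC carries is not given in the sources used here, and any of its sequence that matches the mouse genome would be counted at the mouse position.

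For each library the authors derived their peak lists from the filtered alignment of that library alone, on build mm10, per the notes deposited with the files. The deposited peak lists give a signal value per peak, whose normalization is not stated, and their other score columns are constants. The authors also derived a false discovery rate (FDR) per stretch of bases from the same alignment, and the deposited FDR values lie under 0.05. Footprints had been derived from the alignment and the FDR values of the same library, per the same notes, and the deposited footprint lists carry a p-value or FDR of 0.01 in every line, which was read as the threshold of the list. The aligner, the peak and footprint callers, their versions and the treatment of reads that match several places are not given in the sources used here.

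Each library has 2 peak lists. In the longer list every peak held a base with an FDR under 0.05 and in the shorter list (51901 peaks in replicate 1, 46323 in replicate 2) every peak held a base with an FDR under 0.001. These thresholds were inferred from the FDR values of the same library and are not stated. No source names the list made at the pipeline's own threshold, so the list of narrower peaks was used, as had been fixed for that case before the data were examined. That was the longer list, with a mean width of 199.6 bp against 199.9 bp in replicate 1 and 228.8 bp against 233.3 bp in replicate 2. The difference in width in replicate 1 is small, and the shorter list was run as an alternative throughout.

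Signal values were divided by the step that separates the values of a library to recover counts. Whole multiples were counted with a tolerance of 0.05 of a step. The depth behind a peak is given as this count with a 95% Poisson interval, and shares of peaks and footprints carry 95% Wilson intervals. Intervals cover counting error only. Library totals are not given in the sources used here, so a library size is conditional on values being CPM.

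Coordinates are 1-based on mm10. The reference was assembly GRCm38.p6 with GENCODE M21, and 0 lines of the peak and footprint lists lay on sequences other than the 21 chromosomes used or past a chromosome end. Protein-coding genes numbered 21884. A promoter region overlaps the 1 kb on either side of any transcript start of a protein-coding gene, and a distal region lies more than 1 kb from every such start. The remaining regions were classed as exon, then intron, then intergenic. Peaks of both replicates were merged by an overlap of at least 1 bp, and a merged region with peaks of both replicates is called shared. Its value in a replicate is that of the highest peak.

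Sharing and genomic classes were compared with 100 shuffles of positions within chromosomes by bedtools 2.31.1 with fixed seeds. Footprints were shuffled over all peaks of their own replicate, so that a footprint could land in a different peak. Gene lists for 20 cell types and functions were fixed before the data were examined, with 356 listed genes, of which all but Ahsp, the alpha-globin chaperone gene, matched the annotation. Shared promoter regions of each list were tested against all other protein-coding genes by Fisher's exact test (two-sided). Distal shared regions within 50 kb of a start were tested as the mean per gene against 10000 random lists of the same size (a two-sided permutation test over genes). The random lists were matched on the number of protein-coding gene 5' ends within 50 kb, the gene itself included, in 5 bins. The lowest bin held no gene, and genes with 5 or more 5' ends, the globin genes among them, shared 1 bin. Promoter peaks of the replicates were compared per list by the exact McNemar test (two-sided). P-values were adjusted by the Benjamini-Hochberg method over the 20 lists or the 24 motifs, with a threshold of 0.05.

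Footprints that overlapped between the replicates and lay in a shared region (71075) were extended by 5 bp on each side and searched on both strands for 24 consensus motifs fixed before the data were examined. Each was paired with a window of the same width placed at random in the same region outside all footprints, in up to 20 tries. This left 41996 pairs, and 29079 footprints without room for such a window were not used. Fisher's exact test (two-sided) compared all footprints with all windows as unpaired sets. It did not use the pairing, and footprints of the same region entered separately. For ratios between replicates, values were compared on the log2 scale after the median over all shared regions was set to 0. The median per list was placed among 10000 random gene lists matched on mean value in 10 bins, and a GC correction removed the median ratio in each of 20 bins of GC content.

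Genes were named by a rule fixed before the data were examined. It takes the 3 members of each list with the most distal shared regions, up to 2 members without any shared region within 50 kb, and always Gata1, Tal1, Klf1, Alb, Afp, Alas2 and the globin genes. It also takes the 10 shared regions with the highest mean rank of value, with the gene whose 5' end was nearest. Genes outside the rule are said to have been chosen after their values were seen.

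The procedures were tested on simulated data. With 21884 genes, the promoter test called 82.0% of lists with open promoters at 95% of their genes, 98.4% of lists with 15%, and 1.29% of unchanged lists. The distal test called 88.5% of lists with 3 times as many regions and 1.38% of unchanged lists, also with 21884 genes. The McNemar test was simulated on counts of discordant genes alone. It called 12.9% of lists with 90% of about 8 discordant genes on the same side and 0.0313% of even lists, so it had little power for lists of this size. Over all protein-coding genes the real split was not even, at 395 and 1417. The ratio of a list shifted by -0.2 on the log2 scale fell under the 2.5th percentile in 94.0% of trials with 15542 genes, and that of unshifted lists in 4.0%. The distal and ratio simulations moved values between single genes. Their error rates therefore do not cover lists whose genes share regions, such as the globin list. In 20000 windows the motif test called 4 of 4 planted motifs and 1 of 19 others. The overlap routine gave the same answer as a plain loop for all 12000 intervals tested.

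Alternatives were the shorter peak list, the upper 50% of peaks by value, equal numbers of peaks, autosomes alone, an overlap of at least 50% of both peaks, promoter windows of 500 bp and 2.5 kb, the 5' end of each gene as its only start, gene windows of 20 kb and 100 kb, and no matching on gene density. For footprints they were the narrower ones alone, an overlap of at least 50%, no extension, an extension of 10 bp and control windows shifted by 100 bp. The gene list, class and motif results were also computed without each replicate. Added after the data were seen were the use of 1 gene per cluster (list members within 50 kb of an earlier member left out) and the genomic classes without each replicate. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Read alignments were not analysed here.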

Results

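Chromatin accessibility was measured by DNase-seq, in which DNase I cuts DNA where nucleosomes leave it exposed, in the liver of mouse embryos aged 13.5 days. At this age the liver makes most of the embryo's red blood cells and holds developing hepatocytes beside them. The labels describe a mixed C57BL/6N,129 background, wild type apart from the A85 YAC (a yeast artificial chromosome) in multiple copies. They place both libraries in 1 group, as 2 biological replicates from separate tissue samples with the same donor label. They name no other condition, so regions were compared with chance positions, genes of named cell types with other genes, and replicate 1 with replicate 2. A comparison of the replicates is a comparison of 2 libraries, not of conditions.

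Replicate 1 had 76130 peaks that covered 15.2 Mb, and replicate 2 had 73852 peaks that covered 16.9 Mb. The median peak width was 200 bp in both, and the median peak value was 0.873 in replicate 1 and 0.761 in replicate 2. The scale of these values is not named in the sources used here. Within each library every value was a whole multiple of a fixed step, 0.0127 in replicate 1 and 0.00604 in replicate 2, to within 0.05 of a step in 100% of peaks. Divided by the step, the median peak held 69 counts in replicate 1, with a range of 7 to 12401, and 126 counts in replicate 2, with a range of 7 to 20953. If the values were CPM, the steps would correspond to libraries of 79.0 M and 166 M tags. The intervals given here for single peaks are 95% Poisson intervals of these counts, and like the other intervals they cover counting error only.

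Peaks at the promoters of genes that direct red cell development were present in both replicates. The highest promoter region of Zfpm1, whose product is the partner of GATA factors, had values of 22.5 in replicate 1 and 20.3 in replicate 2, and that of Lyl1, a blood cell helix-loop-helix factor, had 17.3 and 9.62. The corresponding values were 9.58 and 6.03 for Tal1, which encodes the helix-loop-helix factor needed to form blood, 5.29 and 2.76 for the adult globin activator Klf1, and 3.24 and 2.10 for Gata1, the central erythroid factor. Hepatoblast genes varied by the same measure. The albumin gene Alb had no promoter region found in both replicates. The alpha-fetoprotein gene Afp had 1.40 and 1.42 near an internal start, and the forkhead factor gene Foxa3 had 12.0 and 7.93. The peak at the start of Alb had a value of 0.367 (interval 0.246 to 0.527) and that at the start of Afp had 0.468 (0.330 to 0.645), and both were present in replicate 1 alone. Of all peaks of replicate 1, 62.8% (47812; Wilson interval 62.5 to 63.1) overlapped a peak of replicate 2 by at least 1 bp, and of those of replicate 2, 64.2% (47426; 63.9 to 64.6) overlapped a peak of replicate 1. After 100 shuffles of the positions within chromosomes the mean shares were 1.19% and 1.26%, and the highest were 1.31% and 1.37%. The one-sided p of 0.0099 in each replicate is the smallest that 100 shuffles can give.

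Sharing rose with the peak value. Among 5 classes of near-equal size by value, the lowest shared 22.5% of its peaks in replicate 1 and 13.8% in replicate 2, and the highest shared 98.4% and 99.0%. Merging overlapping peaks of both replicates gave 99252 regions, of which 45831 held peaks of both (13.2 Mb, called shared regions here), 28168 held peaks of replicate 1 alone and 25253 of replicate 2 alone. Across the shared regions the values had a Pearson correlation of 0.922 on the log2 scale and a Spearman correlation of 0.889. The median ratio of replicate 2 to replicate 1 was 0.878, which also carries the unnamed scale factors of the libraries. These correlations run across regions, which are not independent replicates, and have no p.

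Of the 10 highest shared regions 9 lay more than 1 kb from the 5' end of every uniquely named protein-coding gene. Starts in this paragraph are these 5' ends, and other transcript starts were not used. Intergenic means outside protein-coding genes. The top region, at chromosome 17 39846781 to 39846900 (mm10, intergenic, 103620 bp from the nearest protein-coding start, that of the pheromone gene Esp38), had values of 157 and 126. An exon of Lars2, the mitochondrial leucyl-tRNA synthetase gene, followed at chromosome 9 123461901 to 123462120 with 87.0 and 63.7 (nearest start Limd1). The other 8, ordered by mean rank, had their nearest starts at Igf2bp3 (intergenic, chromosome 6), Pak3 (intergenic, X), Txndc11 (an intron of Zc3h7a, chromosome 16), Gm8797 (intergenic, chromosome 3), Il31ra (intronic, chromosome 13), Kpna1 (intronic, chromosome 16), Gm15319 (intergenic, chromosome 8) and Gm10717 (an exon of Gm10718, chromosome 9). In 9 of these 10 regions the median 31-base word occurred at least 2 times in the assembly.

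Promoters held a large part of the shared regions. The housekeeping genes Actb, which encodes cytoplasmic actin, and Eef1a1, which encodes a translation elongation factor, had promoter values of 18.02 and 16.4, and 8.51 and 7.45, in replicates 1 and 2. Of the 45831 shared regions, 43.6% (19984) lay within 1 kb of a protein-coding transcription start site, against 4.44% of the same regions after shuffling, 9.82 times as many. Exons outside promoters held 3.26% against 2.74%, introns 24.01% against 34.2%, and intergenic sequence 29.1% against 58.6%. Each of these 4 shares lay outside all 100 shuffles, with an empirical p of 0.0099, the smallest possible, one-sided in the direction of the difference. The small excess in exons did not hold with a promoter window of 2.5 kb, where 2.26% of regions lay in exons (permutation p = 0.0792).

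Genes of red blood cells, apart from the globin genes, had open promoters almost throughout. All 16 listed erythroid transcription factor genes had a shared region within 1 kb of a transcription start site, among them Gata1, Tal1, Klf1, Zfpm1 and Lyl1. So did all 20 genes of the red cell membrane and its receptors, with values of 10.1 and 5.05 at Slc4a1, which encodes the anion exchanger band 3, 9.45 and 6.60 at Sptb, which encodes beta-spectrin, and 1.43 and 1.099 at the water channel gene Aqp1. Of 18 genes for heme synthesis and iron handling, 16 had such a region, with values of 11.9 and 9.91 at Alad, which encodes an early enzyme of heme synthesis, 15.2 and 13.1 at the iron transporter gene Slc11a2, and 19.6 and 11.8 at the biliverdin reductase gene Blvrb. Alas2, which encodes the erythroid enzyme that starts heme synthesis, had no shared promoter region, although a peak of replicate 2 alone lay at its promoter. Of the 9 globin genes 5 had a shared promoter region, with values of 6.52 and 3.02 at Hbb-bs, 4.54 and 2.47 at Hbb-bt, 2.09 and 1.41 at Hba-a1, 6.54 and 5.69 at Hbq1b, and 4.18 and 3.85 at Hbq1a. Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Hbq1a and Hbq1b are near-identical copies, and their separate values are uncertain because the treatment of reads that match both copies is not given in the sources used here.

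Genes of most other cell types had fewer open promoters than the 58.4% of other protein-coding genes. Of 23 genes of adult hepatocyte metabolism 3 had a shared promoter region, Hpd (a tyrosine breakdown enzyme, 5.76 and 4.18) among them, and the urea cycle gene Cps1 and the drug metabolism gene Cyp2c29 had no shared region within 50 kb. Hepatoblast genes stood between these groups, with 12 of 27, among them Foxa3 (a forkhead factor of liver and gut, 12.0 and 7.93), the iron carrier transferrin gene Trf (1.00 and 1.07) and Afp, whose region at chromosome 5 90500841 to 90501020 (1.40 and 1.42) lies in an intron 511 bp from an internal start. Hnf4a, the hepatocyte nuclear receptor gene, had none. Of 20 macrophage genes 5 had a shared promoter region, and the lysozyme gene Lyz2 and the phagocytic receptor gene Timd4 had no shared region within 50 kb. Of 19 endothelial genes 3 had a shared promoter region, including Egfl7 (an endothelial secreted factor, 1.03 and 1.88). The endothelial genes Emcn and Sox17 had no shared region within 50 kb, nor did the mast cell receptor gene Fcer1a, the granulocyte protease gene Ctsg and the T cell gene Cd8a.

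Against all 21884 protein-coding genes, of which 12774 had a shared promoter region, Fisher's exact test (two-sided, adjusted by Benjamini-Hochberg over the 20 lists) gave a higher share in 4 lists and a lower share in 9. By this exact test the 4 were the erythroid membrane and receptor genes (100%, 20 of 20, adjusted p = 0.000286), the erythroid transcription factors (100%, 16 of 16, 0.000710), heme synthesis and iron (88.9%, 16 of 18, 0.0118) and the housekeeping genes (100%, 19 of 19, 0.000286). The heme list was not past the threshold when only the 5' end of each gene counted as a start (exact test, adjusted p = 0.0702). The lower shares were those of adult hepatocyte metabolism (13.04%, adjusted p = 0.000272), granulocyte and mast cell (11.1%, 2 of 18, 0.000286 by the exact test), endothelial (15.8%, 3 of 19, 0.000710), heart and skeletal muscle and likewise gut and pancreas (12.5%, 2 of 16 each, 0.000977), germ cell (14.3%, 2 of 14, 0.00326), macrophage (25%, 5 of 20, 0.00988), bile duct epithelium (16.7%, 2 of 12, 0.0101) and epidermis (21.4%, 3 of 14, 0.0103). With the peaks of 1 replicate alone the bile duct list was not called in either, the endothelial list not in replicate 2 (exact test, adjusted p = 0.446) and the epidermis list not in replicate 1 (0.138). By the same exact test the shares were not called for globin genes (55.6%, adjusted p = 1), hepatoblast (44.4%, 0.215), megakaryocyte (47.4%, 9 of 19, 0.398), stem and progenitor cell (73.3%, 11 of 15, 0.354), lymphoid and also stellate and mesenchymal (35%, 7 of 20 each, 0.0546) and neural genes (10 of 20, 0.526). With the peaks of replicate 2 alone, 77.8% of hepatoblast genes and 75% of stellate and mesenchymal genes had a promoter peak, above the 65.3% of other genes, and neither was called. The lymphoid list and the stellate and mesenchymal list were each called lower in 4 of 7 alternatives, the hepatoblast list in 1, and the stem and progenitor cell list was called higher in 1. A share of open promoters near that of all genes does not show that a cell type is absent or present.

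**Figure D1:**
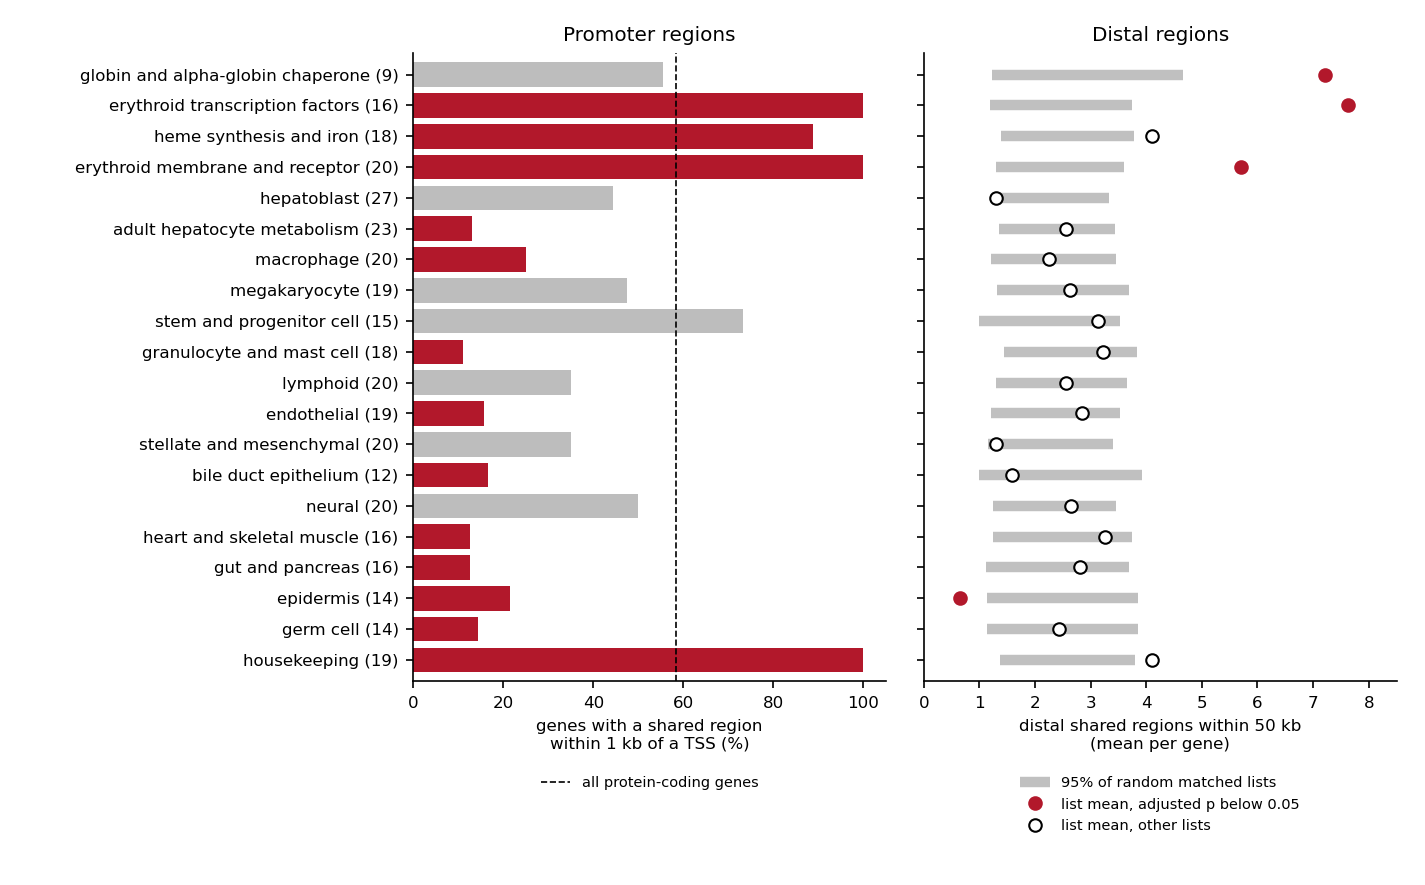
Left, percent of the genes of each list (number of genes in brackets) with a region shared by both replicates within 1 kb of a transcription start site, with the share among all protein-coding genes as a dashed line and lists with an adjusted p below 0.05 in red. Right, mean number of distal shared regions within 50 kb per gene, with the range of 95% of 10000 random lists matched on gene density in grey; red points have an adjusted p below 0.05. All 4 erythroid lists and the housekeeping list lie above their range, and the epidermis and hepatoblast lists below it; 3 of the erythroid lists and the epidermis list are red.

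Shared regions away from promoters were densest around erythroid genes. Zfpm1 had 21 distal shared regions within 50 kb of its start sites, the band 3 gene Slc4a1 had 19, Lyl1 13, Sptb 12, Tal1 11, Alad 11, Gata1, Slc11a2 and Aqp1 9 each, Blvrb 8, Alas2 4 and Klf1 2. Around the alpha-globin cluster Hba-a2 had 11, and Hba-a1, Hba-x, Hbq1a and Hbq1b had 10 each. Around the beta-globin cluster Hbb-y, Hbb-bh1 and Hbb-bs had 4 each and Hbb-bt had 2. These counts depend on the peaks used. Hbb-bs had 20 with the peaks of replicate 1 alone, 5 with those of replicate 2 alone and 1 with the shorter list, Zfpm1 26, 47 and 14, Slc4a1 27, 32 and 8, Aqp1 13, 38 and 5, and Gata1 11, 13 and 4. The albumin gene Alb and Afp had 0, while the hepatocyte factor gene Hnf4a had 5, Foxa3 4 and Trf 3. Among genes of other types, the myelin gene Mbp had 15, Hpd 13, the brush border gene Vil1 10, and the Fc receptor gene Fcgr1, the myeloperoxidase gene Mpo, Actb and Eef1a1 9 each. Distal regions within 50 kb belong to a gene by distance alone and may lie within or nearer to another gene.

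The mean over all protein-coding genes was 2.32 of the 25847 distal shared regions. Erythroid transcription factor genes had 7.63 on average against 2.30 in random lists matched on local gene density (3.31-fold, all 16 genes with at least 1, adjusted permutation p = 0.0020). Erythroid membrane and receptor genes had 5.70 against 2.34 (2.44-fold, 19 of 20 genes with any, adjusted permutation p = 0.0020), and globin genes 7.22 against 2.66 (2.72-fold, adjusted p = 0.0040). The unadjusted p of 0.00020 behind the lists at 0.0020 is the smallest that 10000 random lists can give in this two-sided test, and Benjamini-Hochberg adjustment ran over the 20 lists. The globin value rests on 2 gene clusters whose members share regions, and it was not called with the shorter peak list (adjusted permutation p = 0.126) or a window of 100 kb (0.0888). The epidermis list had 0.643 against 2.35 (adjusted permutation p = 0.0140, 5 of 14 genes with any), and the keratin genes Krt14 and Krt15 had 2 distal regions each, Lgals7 3, and the desmosome genes Dsg3 and Dsc3 none. Its adjusted p was above 0.05 in 6 of the alternatives, up to 0.202 with a window of 100 kb.

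The other 16 lists were not called in this test. Heme synthesis and iron genes had 4.11 against 2.43 (adjusted permutation p = 0.0773), housekeeping genes 4.11 against 2.41 (0.0773) and hepatoblast genes 1.296 against 2.25 (0.0908). The heme list was called with a window of 20 kb (2.30-fold, adjusted permutation p = 0.0150) and with the upper 50% of peaks (2.11-fold, 0.0360). The remaining means were 1.3 for stellate and mesenchymal genes (Col1a1, Col1a2 and Reln 4 each, Col3a1 and Dcn none) and 3.13 for stem and progenitor cell genes (Runx1 8, Flt3 7, Gata2 5), both with an adjusted p of 0.340. They were 3.25 for heart and skeletal muscle (Tnnt2 8, Myl2 7, Myh3 6, Myf5 none; 0.385), 3.22 for granulocyte and mast cell (Mpo 9, Prtn3 7, Cebpe 7; 0.462) and 2.84 for endothelial genes (Eng 8, Egfl7 7, Pecam1 6; 0.556). They were 2.81 for gut and pancreas (Vil1 10, Muc2 7, Cdx2 5, Ins1 and Amy2a5 none; 0.563), 1.58 for bile duct epithelium (Cdh1, Epcam and Muc1 3 each, Cftr and Pkhd1 none; 0.563) and 2.65 for neural genes (Mbp 15, Neurod2 5, Syp 5, Sox1 none; 0.591). They were 2.57 for adult hepatocyte metabolism (Hpd 13, Sds 8, Pck1 7; 0.738), 2.63 for megakaryocyte (Gp9 7, Vwf 7, Nbeal2 6; 0.766) and 2.55 for lymphoid genes (Cd79a 7, Zap70 5, Tcf7 4; 0.789). Germ cell genes had 2.43 (Tnp1 6, Pou5f1 4, Stra8 4, Piwil1 none; 0.885) and macrophage genes 2.25 (Fcgr1 9, C1qb 5, C1qa 4; 0.931).

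At the beta-globin locus the highest region lay upstream of the embryonic gene Hbb-y, 7785 bp from its start, at chromosome 7 103861001 to 103861200 (mm10, intergenic). Its value was 11.2 in replicate 1 (interval 10.5 to 12.0) and 7.18 in replicate 2 (6.78 to 7.60). The upstream intergenic regions at 103859181 to 103859400 (3.86 and 0.869), 103865781 to 103866020 (3.58 and 0.718) and 103870801 to 103870980 (3.11 and 0.863) were also shared. The promoter region of the adult gene Hbb-bs, 103827861 to 103828100, had 6.52 (5.97 to 7.11) and 3.02 (2.76 to 3.29). No shared region lay within 1 kb of the embryonic genes Hbb-y and Hbb-bh1. Within 50 kb of the 4 Hbb genes 7 regions were shared, 16 were in replicate 1 alone and 2 in replicate 2 alone. Whether the YAC, present in multiple copies, shares sequence with this locus is not given in the sources used here, so reads from it cannot be ruled out in these values and counts. These 16 had values of 0.468 to 3.28, and most of them lay downstream of Hbb-bt.

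**Figure D2:**
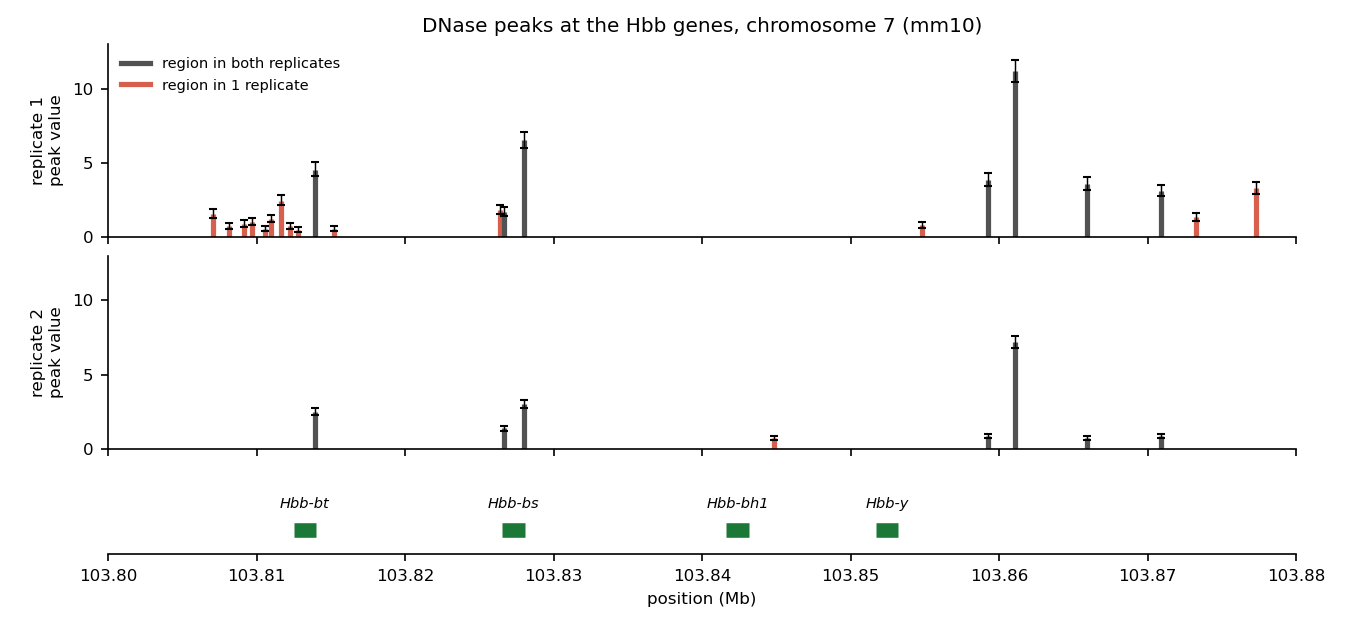
DNase peak values (scale not named) of each replicate along chromosome 7 at the Hbb genes (mm10, position in Mb), with 95% Poisson intervals; grey lines are regions with peaks of both replicates and red lines regions with a peak of 1 replicate. The region at 103861001 is the highest in both replicates, at 11.2 and 7.18.

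At the alpha-globin locus 23 regions were shared, 5 were in replicate 1 alone and 15 in replicate 2 alone. The gene Nprl3, whose introns hold enhancers of the alpha-globin genes, contained shared intronic regions at chromosome 11 32245681 to 32245980 (8.73 and 3.78) and 32250941 to 32251420 (8.62 and 1.93). Near Tal1 an intergenic region at chromosome 4 115095681 to 115096160, nearest to the start of Pdzk1ip1, had 13 and 6.94, and the Tal1 locus had 16 shared regions, 1 in replicate 1 alone and 10 in replicate 2 alone. An exonic region of Klf1 at chromosome 8 84903081 to 84903320 had 8.78 and 6.47. An intronic region of Gata1, 3471 bp from a start at X 7971381 to 7971620, had 5.56 and 3.01. An intronic region of Alas2 at X 150549661 to 150549960 had 3.92 and 1.497. At the albumin and alpha-fetoprotein locus 1 region was shared, 2 were in replicate 1 alone and 0 in replicate 2 alone. The regions given coordinates in these loci were chosen after their values were seen, within loci that were fixed before.

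Footprints, short protected stretches inside accessible DNA, were listed at 151079 positions in replicate 1 and 230992 in replicate 2, with a median width of 10 bp in both. In replicate 1 88.9% of them lay in a peak of the same library, and in replicate 2 81.4%. Of the footprints within peaks, 54.1% in replicate 1 (72656; Wilson interval 53.8 to 54.4) and 36.9% in replicate 2 (69418; 36.7 to 37.1) overlapped a footprint of the other replicate. Placing the footprints at random over all peaks of the same replicate gave 21.5% and 15.5% on average, and the one-sided p of 0.0099 is the smallest that 100 shuffles can give. The shuffles also moved footprints into peaks that the other replicate lacks. The excess therefore mixes the sharing of peaks with the agreement of positions within them. With an overlap of at least 50% of both footprints the shares were 37.3% and 26.7%, against 6.10% and 4.51% by chance, and for the narrower footprints alone 13.8% and 9.79%, against 5.88% and 4.59%. Footprints of both replicates that overlapped numbered 77646 after merging, of which 71075 lay in shared regions and 41996 had a control window of the same width in the same region.

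Motifs of erythroid factors and of general promoter factors were more frequent in shared footprints than in the control windows. The CACCC motif bound by KLF factors occurred in 4.37% of 41996 footprints against 0.614% of controls (7.12-fold, exact test, adjusted p = 8.7e-299). The consensus used for it also accepts the core of the GC box, so its matches cannot be read as KLF sites alone. The GATA motif occurred in 1.34% against 0.512% (2.61-fold, 3.2e-36), the E-box CAGATG bound by helix-loop-helix factors such as the Tal1 product in 0.936% against 0.455% (2.06-fold, 1.0e-16), and the motif of NFE2 and small MAF factors in 0.305% against 0.0190% (16-fold, 2.1e-28). The motif of CTCF, which shapes chromosome loops, occurred in 3.86% against 0.00952%, and the GC box of SP factors in 3.49% against 0.174% (20.1-fold), both with a p that the computer rounded to 0. The other called motifs were ETS (0.748% against 0.240%, 4.3e-26), NFY (1.16% against 0.738%, 8.6e-10, but not called with no extension, 0.272), AP1 (0.710% against 0.383%, 3.4e-10) and REST, a repressor of neural genes (0.207% against 0.0476%, 9.9e-11). The AP1 consensus lies inside that of NFE2 and MAF. The 128 footprints and 8 control windows with the NFE2 and MAF motif are therefore also counted among the 298 and 161 with AP1. Enrichment of AP1 apart from that motif was not tested. NRF1 (0.360%, 3.7e-45) and ZNF143 (0.0571%, 2.4e-07) had 0 matches in the controls, a count that allows up to 0.00714%. With replicate 1 left out the folds were 1.51 for GATA (0.499% against 0.330%), 7.69 for NFE2 and MAF, 9.995 for SP and 1.23 for AP1, all still called. Over all 5 alternatives they ranged from 1.51 to 2.996 for GATA, 4.89 to 13.1 for CACCC, 1.62 to 2.84 for the E-box, 7.69 to 30 for NFE2 and MAF, 96.4 to 1327 for CTCF and 9.995 to 42.9 for SP. The ranges were 2.34 to 4.61 for ETS, 1.09 to 2.51 for NFY, 1.23 to 2.11 for AP1, 3.74 to 8.62 for REST and 0.0984 to 0.548 for FOX. Of the 24 motifs, 12 were more frequent in footprints and 1, that of forkhead (FOX) factors, less frequent (0.0286% against 0.119%, 2.2e-06), by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment.

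The other 11 motifs were not called. For liver factors the shares were 0.0238% against 0.0167% for HNF4 (exact test, adjusted p = 0.755) and 0.0238% against 0.0119% for CEBP (0.402). HNF1 had 0 matches on either side. Its consensus also had 0 matches in the shared promoter and distal regions as a whole, so this comparison says nothing about HNF1 footprints. The shares were 0.140% against 0.171% for PU.1 (0.402), 0.176% against 0.148% for RUNX (0.436), 0.107% against 0.105% for YY1 (1), 0.0571% against 0.0619% for the MYOD E-box (0.968) and 0.0286% against 0.0357% for MEF2 (0.801). They were 0.0667% against 0.100% for OCT (0.191), 0.0190% against 0.0357% for SOX (0.315) and 0.0119% against 0 for RFX (0.107). YY1 was called more frequent in 4 of 5 alternatives and OCT less frequent in 3, and PU.1 was called in 3, in both directions. The tests count footprints of 2 libraries, which are not independent replicates, and a fixed consensus finds only part of the sites of a factor.

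Distal and promoter footprints differed in their motifs. Among 18903 distal footprints 2.51% held a GATA motif against 0.381% of 23093 promoter footprints (exact test, adjusted p = 3.3e-83), and for CTCF the shares were 7.76% and 0.663% (p rounded to 0). The NFE2 and MAF motif (0.608% and 0.0563%, 4.1e-26), the E-box CAGATG (1.65% and 0.355%, 4.6e-43), AP1 (1.28% and 0.242%, 3.4e-37), RUNX (0.302% and 0.0736%, 5.8e-08), REST (0.317% and 0.117%, 1.3e-05) and the MYOD E-box (0.0952% and 0.0260%, 0.00574) were also more frequent in distal footprints. The promoter side was higher for the GC box of SP factors (5.33% against 1.24%, 1.4e-125), the CACCC motif (4.84% against 3.804%, 4.3e-07), ETS (1.23% against 0.164%, 1.4e-41), NFY (1.76% against 0.423%, 2.6e-40), NRF1 (0.559% against 0.116%, 4.4e-15), YY1 (0.182% against 0.0159%, 5.8e-08) and ZNF143 (0.0996% against 0.00529%, 2.4e-05). Part of these differences also lay in the control windows, which held GATA in 0.883% of distal and 0.208% of promoter windows, the E-box CAGATG in 0.693% and 0.260%, AP1 in 0.555% and 0.242%, ETS in 0.101% and 0.355%, and NFY in 0.354% and 1.05%. Over its controls the GATA motif was 2.84-fold in distal and 1.83-fold in promoter footprints. RUNX, the MYOD E-box and YY1 were not called over the controls on their higher side. Distal footprints and controls held RUNX in 0.302% and 0.222% (adjusted p = 0.317 by the exact test) and the MYOD E-box in 0.0952% of both, and promoter footprints and controls held YY1 in 0.182% and 0.165% (0.891). These were two-sided Fisher's exact tests adjusted over the 24 motifs, and the split was chosen after the data were seen.

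**Figure D3:**
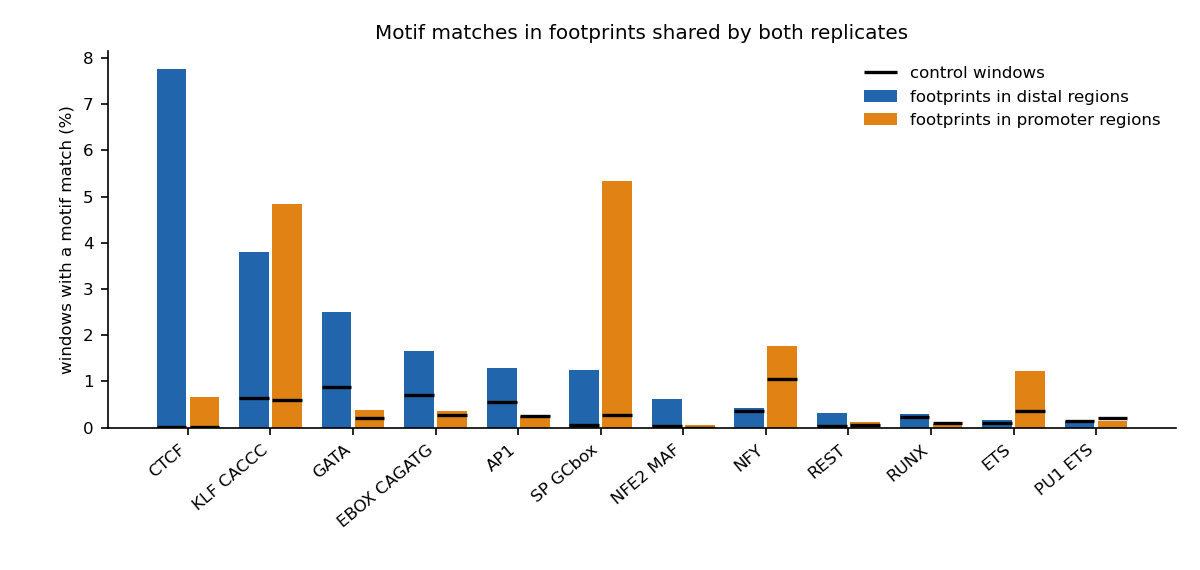
Percent of shared footprints with a match to each motif in distal (blue) and promoter (orange) regions, for the 12 motifs most frequent in distal footprints; black lines mark the control windows of each. CTCF reaches 7.76% in distal footprints and the GC box of SP factors 5.33% in promoter footprints.

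Between the replicates, promoter peaks differed most in number for genes of hepatoblasts, stellate cells and endothelium. In replicate 2 alone, peaks lay at the promoters of the hepatoblast genes Ahsg, Apoa1, Fga, Fgg, Hnf4a, Nr1h4, Onecut1, Ttr and Vtn, which encode plasma proteins and liver factors, and in replicate 1 alone at those of Alb, Fgb and Foxa2. Of the endothelial genes, Esam, Flt1, Ramp2, Sox17, Sox18, Tek and Tie1 had such a peak in replicate 2 alone and Cdh5 in replicate 1 alone. Of the stellate and mesenchymal genes 8 (Acta2, Col3a1, Hand2, Lum, Postn, Tcf21, Twist1 and Wt1) had it in replicate 2 alone and 2 (Pdgfrb and Tagln) in replicate 1 alone. The exact McNemar test (two-sided, adjusted by Benjamini-Hochberg over the 20 lists) called 0 lists, and 0 had an unadjusted p under 0.05. The lowest was 0.0703 for the endothelial genes (1 against 7, adjusted p = 0.973 by the exact test), followed by 0.109 for stellate and mesenchymal genes and 0.146 for hepatoblast genes. Over all protein-coding genes 395 had a promoter peak in replicate 1 alone, 1417 in replicate 2 alone and 12871 in both, so replicate 2 held more such genes over the whole annotation. The hepatoblast, stellate and endothelial lists lean the same way as all genes, while the test assumes an even split. Their counts therefore do not show a shift of these cell types. The genes named here were chosen after their values were seen.

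Peak values of globin genes, and of the 4 erythroid lists pooled, were lower in replicate 2 than those of matched genes, but not those of each erythroid list. With the median log2 ratio of replicate 2 to replicate 1 over all shared regions set to 0, the distal regions of the 9 globin genes had a median of -0.43, lower in 9 of 9 genes, at the 0.735th percentile of 10000 random gene lists matched on mean value (95% of them between -0.36 and 0.15). After the trend with GC content was removed the globin list lay inside its random range, at -0.30 in distal regions (range -0.33 to 0.16, 4.29th percentile). In promoter regions it moved from -0.38 (range -0.27 to 0.37, 5 genes) to -0.27 (range -0.31 to 0.28, 4.72nd percentile). In both the median moved toward 0. The globin genes form 2 clusters whose members share distal regions, so 9 of 9 genes and the percentile rest on about 2 loci. The 4 erythroid lists together had -0.23, against -0.09 in random lists, with 50 of 61 genes lower, at the 0.57th percentile in distal regions, and -0.15, against 0.04, with 39 of 57 genes lower, at the 0.01st percentile in promoter regions. Among single lists, erythroid membrane and receptor genes lay at the 0.25th percentile in promoter regions (-0.18, 17 of 20 genes lower) and at the 20.6th in distal regions (-0.17). Erythroid transcription factor genes lay inside their range in distal regions (-0.21, 13 of 16 genes lower, 11.9th percentile) and in promoter regions (0.02, 6 of 16 lower, 33.0th percentile). So did heme synthesis and iron genes, with -0.27 (14 of 17 lower, 4.71st percentile) and -0.14 (12 of 16 lower, 7.59th percentile), although with the GC trend removed their promoter regions lay below the range (-0.28, range -0.26 to 0.04, 1.31st percentile). Hepatoblast genes (0.28, 99.9th percentile) and neural genes (0.20, 97.7th percentile) were higher in replicate 2 in distal regions, and endothelial genes in promoter regions (1.06, 98.7th percentile, 3 genes). The distal median of the endothelial genes went the other way (-0.12, 9 of 15 lower, 33.0th percentile), and with the GC trend removed the neural genes lay at the 80.8th percentile. Removing it put lymphoid genes above their range in distal regions (0.29, range -0.22 to 0.22, 99.5th percentile). The percentiles describe these 2 libraries, are not p-values, and were computed after the difference was seen.

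**Figure D4:**
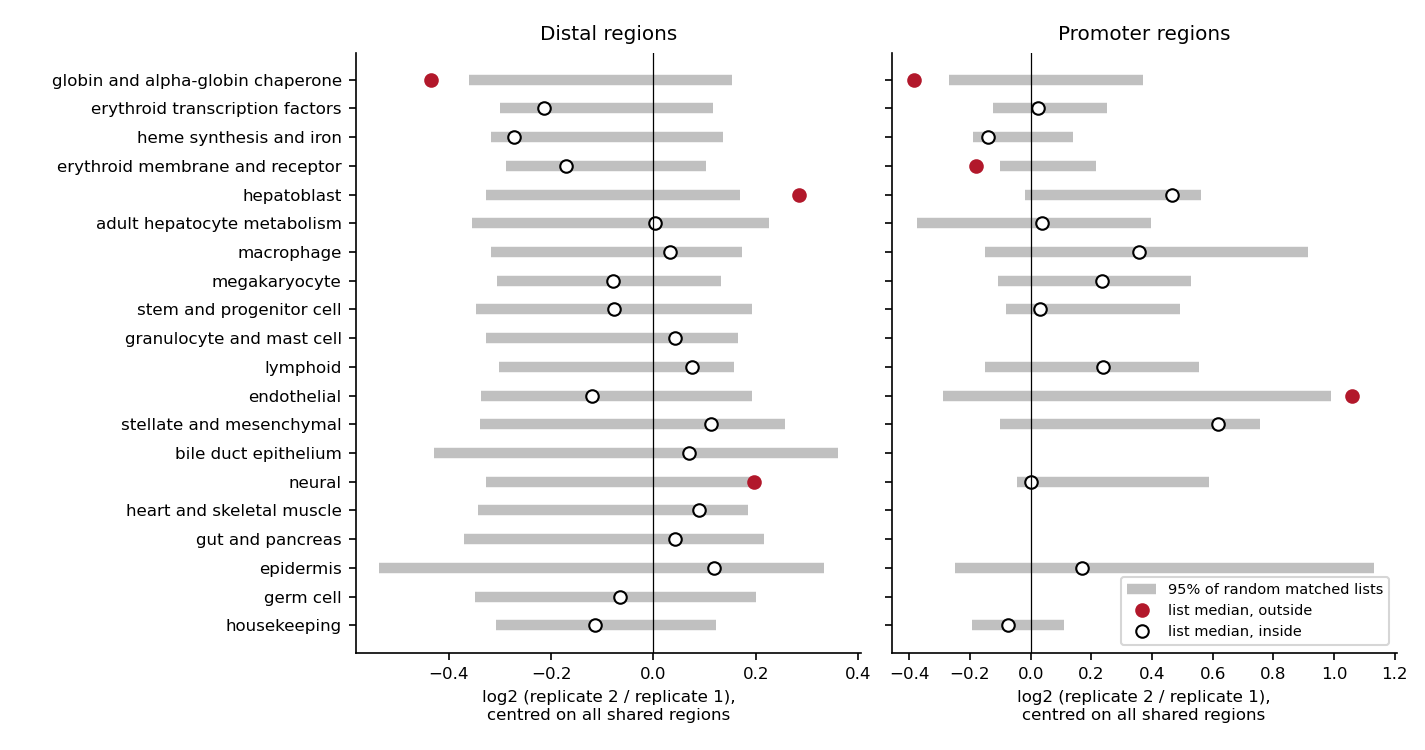
Median log2 ratio of replicate 2 to replicate 1 per gene list, centred on all shared regions, in distal (left) and promoter (right) regions; grey bars span 95% of 10000 random lists matched on mean value, and red points lie outside them. The globin list lies below its range on both sides, at -0.43 and -0.38.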

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

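The use of 1 gene per cluster and the genomic classes without each replicate were chosen after the data were seen, and the other alternatives before. Of 1152 values recomputed under an alternative, 848 stayed the same and 227 moved (214 of them the numbers of distal regions of single genes). A further 26 passed the threshold, 15 lost it and 36 changed direction. A test result counted as the same if it kept its direction and side of the threshold. A count did so if it changed by less than a fixed factor, and a correlation if it stayed within the confidence interval of the main value. Unless a reason is given, the cause was not tested. No paired analysis was possible because the 2 libraries form 1 group and their replicate numbers pair nothing. Leaving out a replicate gives no value for sharing or for the agreement of values. The globin list with 1 gene per cluster gives no value.

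The erythroid transcription factor, erythroid membrane and housekeeping lists were called higher in promoters under all 7 alternatives run, with an adjusted p of at most 0.00570, and the first 2 of these in distal regions under all 8, with at most 0.010. The shorter list held 46323 peaks in replicate 2 and the upper 50% of peaks by value gave 29081 shared regions, in both cases because fewer peaks enter. With an overlap of at least 50% the Spearman correlation was 0.907 and the Pearson correlation 0.932. With a promoter window of 2.5 kb the share of exons was 2.26% (permutation p = 0.0792), and promoters take in many exons there.

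In promoters, as percentage points against other genes, the heme list stood at 24.1 with the 5' end alone (exact test, adjusted p = 0.0702). The globin list changed sign to 1.85 with the 5' end alone and 4.43 with the upper 50% of peaks, and neural genes to 13.6 with a window of 2.5 kb, and none of these was called. Without replicate 2 and without replicate 1 respectively, the differences were -5.07 and 1.38 for globin, -5.07 and 12.5 for hepatoblast, -39.6 and -12.7 for endothelial, -15.6 and 9.72 for stellate and mesenchymal, -27.3 and -6.96 for bile duct, and -24.9 and -29.6 for epidermis. The lists called in the main comparison that lost the threshold there were the bile duct list in both (exact test, adjusted p = 0.114 and 0.847), the endothelial list without replicate 1 (0.446) and the epidermis list without replicate 2 (0.138). Lists not called in the main comparison that were called lower were lymphoid (exact test, adjusted p = 0.0313 with 2.5 kb, 0.00630 with the 5' end alone, 0.00839 with the upper 50% of peaks, 0.0164 without replicate 1), stellate and mesenchymal (0.0310 with 500 bp, 0.0190 with the 5' end alone, 0.00839 with the upper 50%, 0.00536 with the shorter list) and hepatoblast (0.0451 with the shorter list). The stem and progenitor list was called higher without replicate 1 (0.0409).

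In distal regions, as regions per gene against random lists, the globin list stood at 4.16 with a window of 100 kb (adjusted permutation p = 0.0888) and 2.12 with the shorter list (0.126), against 0.00133 to 0.0160 under its other alternatives. The epidermis list stood at -0.794 with 20 kb, -1.72 with 100 kb, -1.07 with the upper 50% of peaks, -0.931 with the shorter list, -2.27 without replicate 1 and -2.01 without replicate 2, with an adjusted p of 0.0753 to 0.202, so that the number of lists called lower was 0 in each of these 6. It was called with no matching on gene density (0.010) and with 1 gene per cluster (0.0177). The heme list was called higher with 20 kb (adjusted permutation p = 0.0150) and with the upper 50% of peaks (0.0360), and the stem and progenitor list without replicate 1 (0.0147).

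Lists that were not called in distal regions changed sign as follows. With the shorter list the values were -0.0607 for adult hepatocyte metabolism, -0.165 for endothelial and -0.0356 for germ cell genes. With 20 kb they were -0.402 for macrophage, -0.127 for granulocyte and mast cell, -0.0411 for heart and skeletal muscle and -0.223 for germ cell genes. With 100 kb the neural value was -0.0322, and the macrophage value was -0.0736 with no matching and -0.205 with 1 gene per cluster. Without replicate 1 and without replicate 2 the values were -0.457 and 0.223 for macrophage, -0.353 and 1.03 for megakaryocyte, -0.102 and 0.308 for lymphoid, 0.0450 and -0.234 for neural, -0.110 and 0.266 for gut and pancreas, and -0.243 and 0.401 for germ cell genes.

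Among motifs, as percentage points against controls, NFY stood at 0.0542 with no extension (exact test, adjusted p = 0.272). The number of motifs less frequent in footprints was 1 in the main comparison, 4 with no extension, 3 without replicate 1 and 2 without replicate 2. Motifs that were not called changed sign to 0.0632 (PU.1, extension of 10 bp), -0.00956 and -0.00421 (HNF4, no extension and 10 bp), -0.0159 and -0.00961 (RUNX, no extension and shifted windows), 0.0168 (the MYOD E-box, shifted windows), 0.0168 (MEF2, shifted windows) and 0.0126 (OCT, 10 bp). Without replicate 1 and without replicate 2 they were -0.0368 and 0.0903 for PU.1, both called (exact test, adjusted p = 0.00481 and 4.3e-06), 0.00789 and -0.00480 for HNF4, -0.0132 and 0.0644 for RUNX, the latter called (0.00314), 0.0132 and 0.000961 for the MYOD E-box, and -0.00592 and 0.00288 for MEF2. YY1 was called more frequent with no extension (exact test, adjusted p = 0.000853), with shifted windows (1.3e-09), without replicate 1 (0.00221) and without replicate 2 (0.0465). CEBP was called more frequent with shifted windows (0.000781) and RFX with no extension (0.0441). Called less frequent were PU.1 (4.5e-07) and SOX (0.00352) with no extension, and OCT with no extension (2.8e-07), without replicate 1 (6.3e-05) and without replicate 2 (0.00558).

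Low peaks were shared least, and whether depth is the cause was not tested. The lowest of 5 classes by value shared 22.5% and 13.8% of its peaks, so the lack of a low peak in either library does not show closed chromatin.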

Other observations

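The split of regions by replicate and all values in the next paragraph were looked at only after the data were seen. So were the comparison on peak height and the test on GC content in promoter regions. The other tests were fixed before their results were seen. The labels name no difference between the replicates, so no biological explanation was tested apart from the share of erythroid cells in the tissue.

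Distal regions of the separate replicates differed in their motifs. A GATA motif lay in 15.5% of 23125 distal regions found in replicate 1 alone, in 13.7% of 25847 shared distal regions and in 2.71% of 17283 found in replicate 2 alone. The CTCF motif lay in 3.68%, 14.8% and 1.28%, and the median GC content was 48.6%, 52.0% and 54.5%. Within shared distal regions, the 3541 with a GATA motif had a log2 ratio of replicate 2 to replicate 1 that was -0.65 against regions of like height without it, and -0.61 with GC content matched as well. The difference was -0.55 for the NFE2 and MAF motif (320 regions), -0.33 for AP1 (1732), -0.28 for RUNX (893) and -0.21 for CACCC (2830; -0.30 with GC matched). Most of the motifs searched had a negative difference. For PU.1 the difference was -0.22 (671 regions, -0.25 with GC matched) and for NFY -0.14 (890 regions, -0.19 with GC matched). It was also -0.21 for the liver-factor motifs HNF4 (95; -0.15 with GC matched) and FOX (429; -0.11 with GC matched), and only -0.04 for the E-box CAGATG (2032). It was 0.29 for CTCF (3824) and 0.37 for REST (209). Some genes at the extremes of 21884 overlapping windows had many regions of 1 replicate alone, and whether these group beyond chance was not tested. Within 50 kb of Hbb-bs 16 regions were in replicate 1 alone and 1 in replicate 2 alone, a difference that 8 of 21884 genes reached (reads from the YAC cannot be ruled out there), and the phosphodiesterase gene Pde4d had 31 against 7. In the other direction Fam213b and Mmel1, neighbours on chromosome 4, had 2 against 80 and 2 against 79, and the limb and axis patterning genes Hoxa3, Hoxa5 and Hoxa6 had 1 against 50. Each gene list had both kinds, with a mean of 8.56 and 8.44 regions per globin gene and 2.28 and 2.46 over all genes. The other erythroid lists had more regions in replicate 2 alone than in replicate 1 alone. In replicates 1 and 2 their means were 3.375 and 8.25 for transcription factors, 4.9 and 8.1 for membrane and receptor genes, and 3.11 and 4.67 for heme genes.

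The 4 erythroid lists pooled had lower values in replicate 2, although the transcription factor list (11.9th percentile in distal and 33.0th in promoter regions) and the heme list (4.71st and 7.59th, but 1.31st in promoters with the GC trend removed) lay inside their random ranges. The pooled distal median log2 ratio, -0.23, lay at the 0.57th percentile of random lists matched on peak height (2.07th with 1 gene per cluster). The difference was itself described against these matched lists, so this comparison is no separate test of height as a cause. Removing the trend with GC content left the promoter median at -0.21 and the 0.02nd percentile (0.03rd with 1 gene per cluster), which argues against GC content as the whole cause in promoters. In distal regions the same correction moved the median with 1 gene per cluster from -0.22, against a random range of -0.21 to 0.04, to -0.14, against -0.15 to 0.08 (4.25th percentile; 2.15th with all genes), so part of the distal difference may follow GC content, and that remains open because the call depends on which genes of a cluster enter. A smaller share of erythroid cells in replicate 2 could raise the other cell types alike, but their distal medians lay at the 33.0th (endothelial), 77.5th (macrophage), 82.6th (stellate) and 99.9th (hepatoblast) percentiles, a spread of 0.41 on the log2 scale that lies at the 85.3rd percentile of random lists, so this explanation is neither excluded nor shown.

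Replicate 2 had more footprints. Shared regions held 3.51 footprints on average in replicate 2 and 2.63 in replicate 1, a ratio of 1.33, and their median count was 205 against 114. At matched counts per region the median ratio over 10 classes was 1.01, with a range of 0.959 to 1.48, where 1.48 is the class of fewest counts and the others reach at most 1.08. Regions were classed by the count of each replicate separately, so a class holds different regions in the 2 replicates, 8201 and 697 in the class of fewest counts. The excess may come from the larger number of counts per region, but the same regions were not compared at equal counts.

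The 10 highest regions may hold reads from several copies of a sequence. In 9 of them the median 31-base word occurred at least 2 times in the assembly, against 4 of 200 random distal regions from the highest 10% by value. The exception was the region nearest to Pak3 on the X chromosome, with a median of 1 copy, and the region nearest to Gm10717 had a median of 44 copies and was 97.3% repeat-masked. In each of the 10, 0% of the words occurred in the mitochondrial genome.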
